A study of Mus musculus with 2 samples.

How the data were processed

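Single-cell RNA sequencing of newborn mouse heart was analysed from 2 libraries, which were technical replicates 1 and 2 of 1 biological sample. The records of both replicates give the same internal library identifier, while the second matrix carries a different one, so each matrix was paired with the record it was deposited under. The hearts were whole hearts of C57BL6 and ICR mice at postnatal day 0, digested with trypsin for 30 min at 37 °C in 6 fractions of 5 min each. Cells were captured with the 10x Chromium Single Cell 3' version 2 chemistry, and each channel was meant to yield between 6000 and 10000 cells. The submitters' processing notes name Cell Ranger 2.1.0 and the mouse assembly mm10. The deposited values were whole-number counts per gene and cell barcode, with no normalisation. Whether a count is a unique molecular identifier (UMI) or a sequencing read is not stated for the matrices, whose name speaks of read counts, so the values are called counts here. Gene symbols, gene types and coordinates came from a GENCODE vM21 annotation of GRCm38, the assembly that mm10 also names. Of 27999 features, 27645 carried a symbol in that annotation and 354 did not. One feature was a reporter, EGFP, with 0 counts. Genes with near-identical copies, such as Hba-a1 and Hba-a2 or Hspa1a and Hspa1b, may have exchanged reads, so their single values are uncertain.

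Barcodes with at least 500 detected genes and 1000 counts were kept, with no limit on mitochondrial counts. Scrublet, run through scanpy 1.11.5 in each technical replicate, called only 1 and 4 barcodes as doublets, or 0.0172% and 0.0673% of barcodes. These were removed, so doublets were in effect not removed. Counts were scaled to 10000 per cell and log-transformed. Mitochondrial genes and all genes of the lists described next were left out of the clustering features. The 2000 most variable genes, 30 principal components and 15 exact nearest neighbours fed Leiden clustering (igraph 0.11.9) at resolution 1.0 with seed 0, with both technical replicates together and no batch correction. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and scikit-learn 1.9.0, and plots were drawn with matplotlib 3.10.9.

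Clusters were named from marker lists for cardiomyocytes, fibroblasts, epicardial cells, vascular endothelium, endocardium, lymphatic endothelium, pericytes, smooth muscle, macrophages, neutrophils or monocytes, B cells, T or NK cells, mast cells, erythroid cells, megakaryocytes or platelets, glia, neurons, epithelium, skeletal muscle and brown adipocytes. A cluster took the name of its best type when the mean over markers of log2(CPM+5), less the mean over clusters, was at least 1. At least 3 markers also had to reach 20 CPM (counts of a gene scaled to a common library total), and an erythroid name needed 5% of counts from haemoglobin genes. A cluster stayed unnamed when more than 2 of its 10 leading genes were markers of another type and exceeded those of its own. Names carry the ending -like because they rest on these markers alone. The clustering and naming were replaced once: exact neighbours took the place of approximate ones, and this scoring rule was chosen after the data were seen.

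Gene lists covered transcription factors, signalling ligands, extracellular matrix, glycolysis, fatty acid oxidation, imprinted growth genes, immediate early genes, heat shock genes, S phase, G2M phase, sarcomere isoform pairs and sex-linked genes. Counts were summed per class and technical replicate and expressed as CPM. Classes with at least 50 kept cells in each technical replicate were compared. A list member passed the size rule in a class when it had at least 20 counts there in each technical replicate and its CPM was at least 2 times that of every other compared class in both. Genes are named by rule: up to 3 passing genes per list and class with the largest ratio to the next class, 10 cardiac factors in every case (Gata4, Gata6, Mef2c, Tbx5, Hand2, Nkx2-5, Tbx20, Tcf21, Wt1 and Tbx18), all isoform and sex-linked genes, and the 5 genes at each end of the technical replicate ratio among those with 500 counts or more. Other genes named in the text were chosen after their values were seen. The cell filter, clustering settings, marker and gene lists, size rule, named-gene rule and most alternatives were fixed before the data were examined.

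For the cell cycle lists, each cell was thinned at random to 2000 counts and called positive with at least 3 counts. Isoform shares are the first gene's part of the summed counts of a pair. Intervals are exact at 95% (Clopper-Pearson for shares, Poisson for counts, and their conditional binomial form for ratios). They cover counting error only. Medians in the technical replicate tests are the exception, with intervals taken from the spread of values across genes and classes. With 1 biological sample there is no biological replication, so no p-value or count of significant genes is given, and the values of both technical replicates stand beside most pooled ones. A share of 0 is given with the upper limit that 3 counts of the total would set. The size rule was tested on simulated data with 27999 genes in 7 classes. It passed 0 of 50 genes raised 1.5-fold and 50 of 50 raised 3-fold, 5-fold or 10-fold, and 0 of the 6651 unchanged genes that had enough counts to pass. The 1.5-fold level lies below the rule's ratio of 2 and the higher levels lie above it, so this outcome largely follows from the rule. It shows that the rule was applied as written, and it gives no error rate for the measured classes.

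Alternatives changed 1 setting at a time, and 2 of them joined 2 choices (genes with counts, variable genes with components): each technical replicate left out; a minimum of 200 genes with no count minimum; barcodes over 20% mitochondrial counts left out; doublet calls kept; resolutions 0.5 and 2.0; list genes kept among the features; 1000 variable genes with 15 components; the mean over cells of each cell's CPM; CPM without mitochondrial and haemoglobin genes; a size rule ratio of 3 or no minimum count. Cycle shares were also computed with thinning to 1000 counts, without thinning and with at least 5 counts. Isoform shares were also averaged over cells with at least 5 counts of the pair. Agreement of the technical replicates was recomputed without a cell filter, with a pseudocount of 0.1 CPM in place of 1, and with genes of at least 10 counts. The sex-linked call was repeated with at least 2 counts, and haemoglobin shares after thinning to 2000 counts. Added after seeing the data were leaving out the 5% of barcodes with the highest doublet score, comparing classes with at least 20 cells, thinning to 1000 counts from genes that are not mitochondrial, approximate neighbours, list totals without the 1 or 2 genes with the most counts in the leading class, ratios without the 1 cluster of a class that held the most counts, and the leading class against the highest cluster of another compared class.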

Results

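Newborn mouse whole heart was profiled as single cells in 1 group, P0 whole heart, with 1 biological sample and 2 technical replicates. Technical replicate 1 held 5888 barcodes with 34668956 counts, and technical replicate 2 held 6047 barcodes with 33871582 counts. The median barcode had 4831 counts and 1674 genes in replicate 1, and 4521 counts and 1570.0 genes in replicate 2. Single barcodes ranged from 1850.0 to 76750 counts. After filtering, 5803 and 5941 cells remained, or 11744 in all. Mitochondrial genes took a median of 29.3% and 30.7% of the counts per barcode, and 64.6% of kept cells were over 20%. The stated purpose of the series was a reference map of newborn heart cells from which to choose transcription factor candidates for lineage conversion.

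The first comparison asked how far the 2 technical replicates of the suspension differed. Across 19566 genes, log2(CPM+1) of the summed counts had a Pearson r of 0.998 and a Spearman rho of 0.991 between them, where genes are not independent replicates. Among 9220 genes with 500 counts or more, 2 differed more than 2-fold and 24 more than 1.5-fold. Angptl7, which encodes a secreted angiopoietin-like protein, was lowest in replicate 1, at 0.400 times its level in replicate 2 (interval 0.331 to 0.481). It was followed by the long noncoding RNA Gm12840 at 0.534 times, the alpha globin gene Hba-a2 at 0.540 times, the ribonuclease gene Rnaset2a at 0.546 times and the nucleoside diphosphate kinase gene Nme2 at 0.548 times. The highest ratio of replicate 1 to replicate 2 was 2.32 (interval 2.05 to 2.62) for the feature ENSMUSG00000063180. Next came the pseudogene Gm10263 at 1.93, the MHC class II invariant chain Cd74 at 1.92, the ribosome biogenesis gene Pdcd11 at 1.65 and the antisense transcript Rab26os at 1.63. The chi-square statistic per degree of freedom was 7.09 over 15533 genes. The 2 libraries hold different cells, which by itself puts this value above 1, so no cause was read from it. They shared 53 barcodes, whose profiles had a median correlation of 0.431, and 100 shuffled pairings gave medians from 0.409 to 0.456.

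The second comparison gave the cell types of the newborn heart. Of 21 clusters, 19 took the names of 9 cell types and 2 stayed unnamed. Cardiomyocyte-like cells were the largest class, with 5397 cells or 46.0% of those kept (interval 45.1 to 46.9, with 49.7% and 42.3% in technical replicates 1 and 2). Fibroblast-like cells made up 11.0% (11.7% and 10.4%) and vascular endothelial-like cells 7.55% (7.24% and 7.86%), though the last rose to 17.1% with a minimum of 200 genes. That setting added only 186 barcodes, so most of the rise came from barcodes that changed name. Vascular endothelial-like cells went from 887 to 2039, and unnamed barcodes from 2904 to 2028. Endocardial-like cells, the inner lining of the chambers, made up 2.92% (2.88% and 2.96%), and smooth muscle-like cells 2.66% (2.65% and 2.66%). The smooth muscle-like share fell to 1.29% at resolution 0.5, and both shares were 7.22% without barcodes over 20% mitochondrial counts. Macrophage-like cells made up 2.1% (2.26% and 1.95%) and pericyte-like cells, which wrap small vessels, 1.94% (2.26% and 1.63%). At resolution 0.5 pericyte-like cells rose from 228 to 387, or 3.30%, while smooth muscle-like cells fell from 312 to 152. The epicardial-like cluster held 93 cells (35 and 58) and the T or NK-like cluster 36 cells (22 and 14), both under the minimum of 50 per technical replicate. The epicardial-like share was 0.792% of all kept cells and 0.603% of those of technical replicate 1. With technical replicate 2 left out and the rest clustered again, it was 0.362%. No cluster took the name of lymphatic endothelium, neutrophils or monocytes, B cells, mast cells, erythroid cells, megakaryocytes or platelets, glia, neurons, epithelium, skeletal muscle or brown adipocytes.

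The 2 unnamed clusters held 24.7% of kept barcodes (20.3% and 29.0%), with a median of 2366 counts and 935 genes, and haemoglobin genes and Alas2 led their profile. Mitochondrial genes took a median of 36.2% of counts in cardiomyocyte-like cells, 37.1% in unnamed barcodes and 3.25% in fibroblast-like cells. Leaving out barcodes over 20% mitochondrial counts kept 4158 cells and reordered the classes, with fibroblast-like cells at 30.1%, cardiomyocyte-like cells at 25.5% and vascular endothelial-like cells at 14.6%. The macrophage-like share fell to between 1.16% and 1.29% in 3 other settings, in which 117 to 132 cells took the name neutrophil or monocyte.

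**Figure D1:**
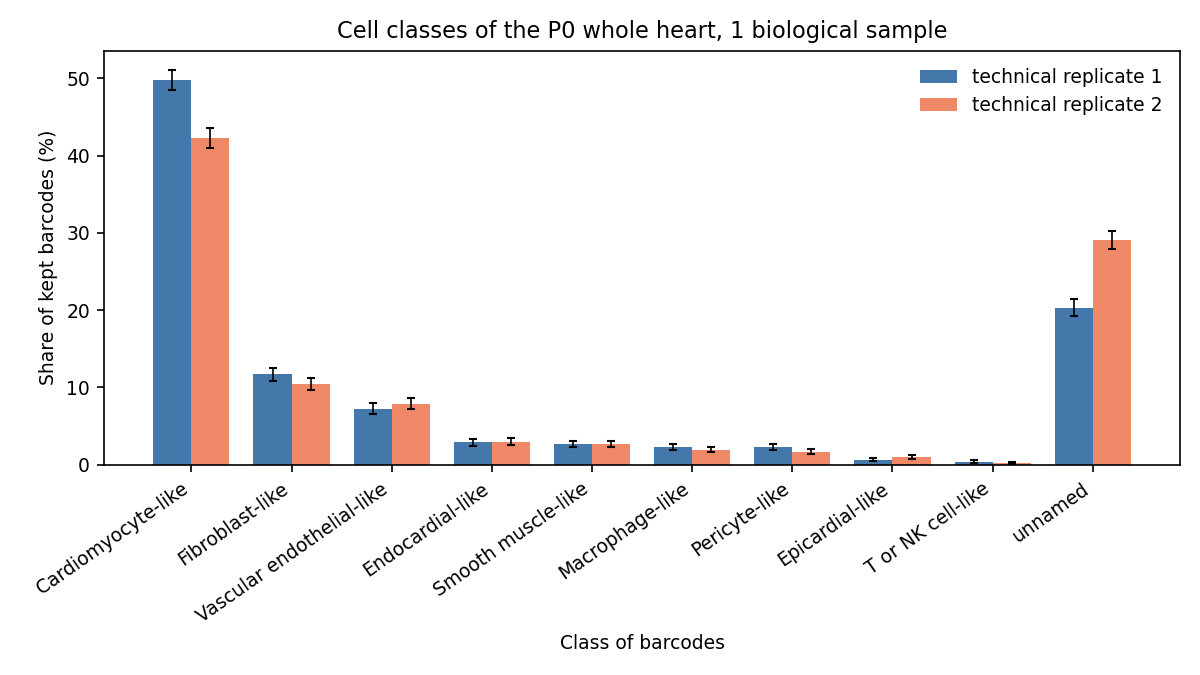
Share of kept cells in each named class, in percent, with 1 bar per technical replicate and exact 95% intervals that cover counting error only. Cardiomyocyte-like cells formed 49.7% and 42.3% in technical replicates 1 and 2, and unnamed barcodes 20.3% and 29.0%.

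The third comparison asked which of 7 classes held the highest level of each transcription factor, the use the series states for this map. Of 106 measured factors, 32 passed the size rule: 8 in cardiomyocyte-like, 7 in endocardial-like, 7 in vascular endothelial-like, 5 in macrophage-like, 3 in fibroblast-like, 1 in pericyte-like and 1 in smooth muscle-like cells. Each ratio that follows is a class's CPM over that of the next highest class, and a range is the span over the 14 alternative settings. In cardiomyocyte-like cells the mitochondrial biogenesis coactivator Ppargc1a stood 9.56 times above the next class (9.26 and 10.0 in technical replicates 1 and 2, range 5.20 to 18.3). The oestrogen-related receptor gene Esrrg followed at 6.08 times (5.59 and 5.14, range 3.57 to 8.50) and the homeodomain-only gene Hopx at 5.48 times (4.90 and 5.77, range 3.03 to 8.03). Irx4, Nkx2-5, Tbx5 and Esrra were among the others that passed there. In endocardial-like cells the forkhead gene Foxc1 was 6.09 times (5.45 and 7.04, range 4.05 to 8.01) and the valve development factor Nfatc1 4.04 times (3.70 and 4.45, range 3.83 to 4.73) the next class.

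Fibroblast-like cells had Sox9, a factor of cartilage and valve mesenchyme, at 24.6 times the next class (19 and 21.9, range 7.38 to 46.8), and Twist2, a mesenchymal factor, at 2.75 times (2.61 and 2.90, range 1.31 to 5.22). Spi1, a myeloid lineage factor, stood at 414 CPM in macrophage-like cells, 218 times the next class (354 and 147, range 3.23 to 544). Maf followed there at 38.3 times (31.4 and 46.4, range 1.5 to 59.6) and the haematopoietic factor Runx1 at 19.4 times (16.0 and 25.1, range 2.53 to 25.4). Spi1 and Runx1 were lowest at resolution 2.0, which separated a neutrophil or monocyte-like class, and Maf was lowest with the epicardial-like class compared. In vascular endothelial-like cells Sox17, an arterial endothelial factor, was 10.6 times (10.7 and 10.5, range 4.57 to 15.5) and Sox18 4.10 times (4.67 and 3.79, range 2.94 to 4.53) the next class. The orphan receptor gene Nr2f1 passed in pericyte-like cells at 3.80 times (4.12 and 3.45, range 2.23 to 4.34), though a cardiomyocyte-like cluster of 82 cells was higher (126 against 107 CPM), and the odd-skipped gene Osr1 in smooth muscle-like cells at 3.30 times (3.62 and 2.96, range 1.62 to 6.82). Of the 358 counts of Osr1 there, 354 came from 1 of the 2 clusters of that class, with 152 cells, and without it the ratio was 0.0705.

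Of the 10 cardiac factors named in every case, Nkx2-5, a homeobox factor of heart muscle (chromosome 17, 26838664 to 26845009 of GRCm38), was highest in cardiomyocyte-like cells at 161 CPM (162 and 160.1), 5.09 times the next class. Tbx5, a T-box factor of the atria and left ventricle (chromosome 5, 119832668 to 119885219), reached 77.5 CPM there (78.3 and 76.7), 3.82 times the next class. Tcf21, an epicardial and fibroblast lineage factor (chromosome 10, 22817281 to 22820174), was highest in fibroblast-like cells at 535 CPM (509.8 and 562), 12.5 times the next class (range 5.88 to 17.2). The T-box factor Tbx20 was also highest there, at 1192 CPM (1163 and 1223) against 639 CPM in cardiomyocyte-like cells. With mitochondrial and haemoglobin genes left out of the total, these levels were 1261 and 988 CPM. Hand2, a basic helix-loop-helix factor of the right ventricle and cushions (chromosome 8, 57320983 to 57324633), reached 241 CPM in endocardial-like cells (245 and 238), 3.53 times the next class (range 2.45 to 3.78). Mef2c, a muscle and vascular factor, was highest in smooth muscle-like cells at 831 CPM (759 and 901), with 594 CPM in pericyte-like cells.

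Wt1, a zinc finger factor of the epicardium (chromosome 2, 105126529 to 105173616), was 4.63 times the next class in vascular endothelial-like cells at 113 CPM (116 and 109), but the small epicardial-like class had 372 CPM, and the ratio became 0.303 when that class was compared. The epicardial T-box factor Tbx18 had 122 CPM in fibroblast-like and 121 CPM in pericyte-like cells, below 380.0 CPM in the epicardial-like class, and pericyte-like cells came first by the mean over cells. Gata4 was spread over endocardial-like (96.5 CPM, 100.3 and 92.7), fibroblast-like (89.4 CPM, 87.0 and 92.0) and cardiomyocyte-like cells (65.8 CPM, 67.2 and 64.2), and by the mean over cells fibroblast-like cells came first. With mitochondrial and haemoglobin genes left out of the total, Gata4 had 104 CPM in endocardial-like cells and 102 CPM in cardiomyocyte-like cells, the next highest class. Gata6 was highest among the 7 classes in endocardial-like cells at 231 CPM (223 and 239), against 208 CPM in smooth muscle-like cells (256 and 162), which came first in technical replicate 1, and 202 CPM in cardiomyocyte-like cells (209 and 196). The epicardial-like class had 281 CPM of Gata6 (217 and 325), and cardiomyocyte-like cells came first at 313 CPM once mitochondrial and haemoglobin genes were left out of the total.

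**Figure D2:**
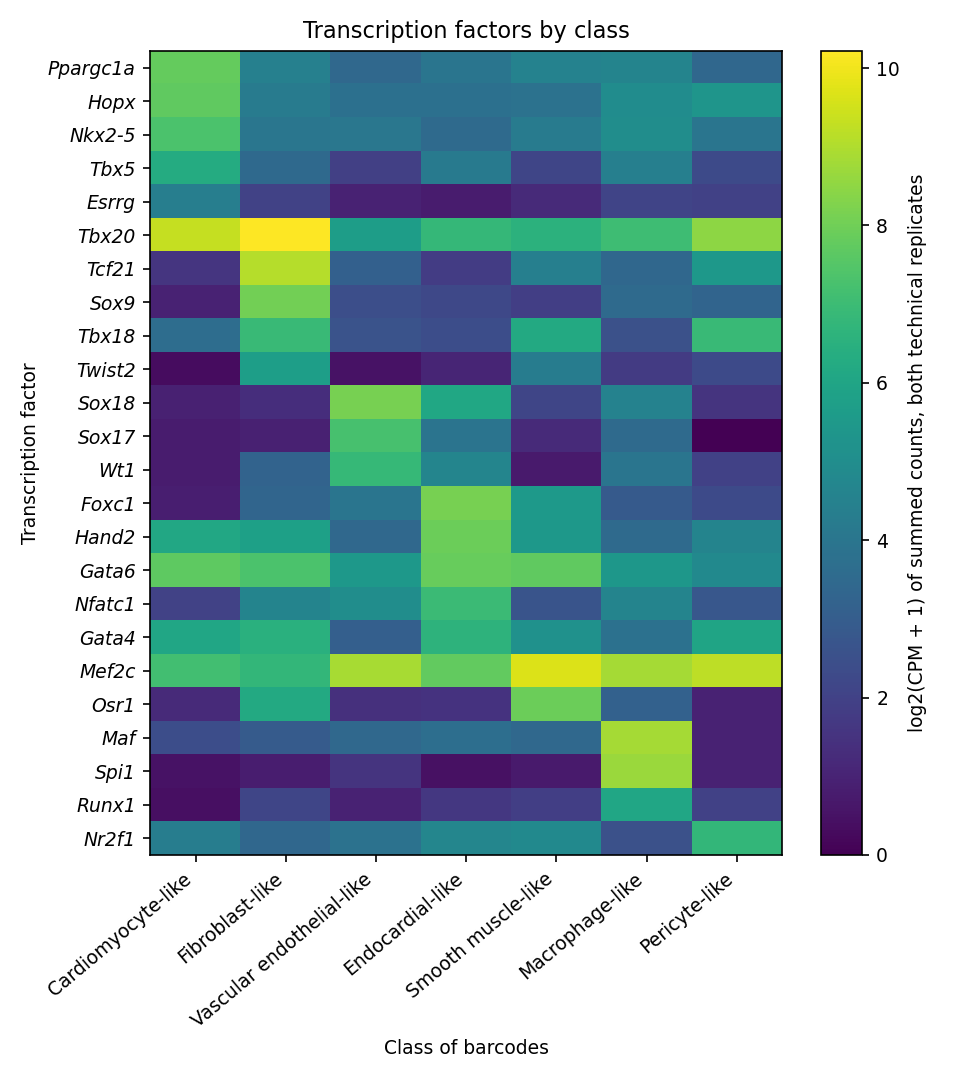
Transcription factors named by rule, 1 line of the heat map per gene and 1 column per compared class, with colour giving log2(CPM+1) of the summed counts of both technical replicates. Factors are ordered by the class in which they were highest, such as Tcf21 at 535 CPM in fibroblast-like, Nkx2-5 at 161 CPM in cardiomyocyte-like and Hand2 at 241 CPM in endocardial-like cells.

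The fourth comparison covered secreted signals, of which 32 of 66 ligand genes passed the size rule, 8 of them in fibroblast-like, 6 in endocardial-like, 5 each in cardiomyocyte-like, smooth muscle-like and vascular endothelial-like, 2 in macrophage-like and 1 in pericyte-like cells. Cardiomyocyte-like cells had the bone morphogenetic protein gene Bmp7 at 12.3 times (11.1 and 5.95, range 4.65 to 17.9) and the trabecular growth signal Bmp10 at 5.75 times (3.70 and 7.91, range 3.30 to 28.7) the next class. Of the 4597 counts of Bmp10 in that class, 4053 came from 1 cluster of 701 cells, and without it the ratio was 0.772. The vessel-stabilising ligand gene Angpt1 followed at 4.52 times (3.76 and 5.21, range 3.72 to 11.8), with 1527 of 2447 counts in the same cluster and a ratio of 1.93 without it (1.70 and 2.1). In endocardial-like cells Nrg1, the neuregulin that signals to heart muscle, was 13.9 times the next class (15.2 and 12.7, range 13.3 to 15.6). The Wnt ligand genes Wnt2 and Wnt4 were 28.6 times (13.4 and 66.4) and 11.5 times (13.7 and 9.04) the next class there, though both ratios fell, to 1.14 and 1.16, with the epicardial-like class compared. The value for Wnt2 rested on 2 counts in the next class (interval 7.76 to 239) and ranged from 12.2 to 69.8 with 1 technical replicate left out. Vascular endothelial-like cells led for the peptide gene Apln at 14.2 times (9.54 and 15.5, range 4.40 to 42.2), the Notch ligand gene Jag2 at 13.9 times (15.6 and 5.28, range 5.52 to 15.7) and the mural cell recruitment signal Pdgfb at 6.73 times (5.82 and 5.71, range 4.73 to 8.12).

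Fibroblast-like cells led for the lymphatic growth factor gene Vegfd at 8.36 times the next class (6.08 and 12.6, range 3.24 to 10.3). Gdf6 was 5.95 times (3.54 and 34.4), with 2 counts in the next class (interval 1.58 to 50.3, range 1.96 to 7.38). The guidance signal Sema3c was 6.13 times (5.34 and 7.11) among the 7 classes, but the epicardial-like class, once compared, was higher (ratio 0.338), as was a cardiomyocyte-like cluster of 91 cells (218 against 82.1 CPM). Smooth muscle-like cells led for the neurotrophin gene Bdnf at 8.60 times (13.0 and 5.12, range 4.74 to 17.0), the chemokine gene Cxcl12 at 4.38 times (4.54 and 4.23, range 3.68 to 7.48) and Angpt2 at 3.32 times (4.62 and 2.12, range 1.91 to 4.90). Of the 71 counts of Bdnf there, 67 came from the cluster of 152 cells, and without it the ratios for Bdnf, Cxcl12 and Angpt2 were 0.925, 1.51 and 2.22. In macrophage-like cells the cytokine gene Il1b was 16.0 times (12.4 and 22.4, range 0.521 to 65.3) and the chemokine gene Ccl2 3.14 times (3.09 and 3.20, range 2.88 to 4.52) the next class, but Il1b was higher in a neutrophil or monocyte-like class where one separated (ratio 0.521), and gave 65.3 without technical replicate 1. Wnt5a was 2.33 times in pericyte-like cells (2.50 and 2.14), and the epicardial-like class was again higher once compared (ratio 0.216), as was a fibroblast-like cluster of 171 cells (93.1 against 62.1 CPM).

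Extracellular matrix genes were concentrated in fibroblast-like and smooth muscle-like cells, which held 11 and 6 of the 19 that passed among 46. Eln, which encodes elastin, reached 21910 CPM in smooth muscle-like cells, 10.9 times the next class (14.3 and 8.14, range 7.45 to 21.9). The elastic fibre gene Fbln5 was 7.49 times (9.70 and 5.51, range 4.91 to 15.6) and the basement membrane gene Lama5 8.86 times (8.80 and 8.81, range 1.12 to 9.62) the next class there. In fibroblast-like cells the collagen genes Col11a1 and Col12a1 were 19.8 times (15.4 and 18.9, range 6.98 to 44.0) and 5.78 times (5.19 and 6.46, range 4.13 to 6.26) the next class, and the hyaluronan synthase gene Has2 was 11.8 times (13.6 and 6.05) with 1 count in the next class (interval 2.06 to 471). The values for Eln and Fbln5 belonged to the smooth muscle-like cluster of 152 cells, with 31632 of 32725 and 2858 of 2875 counts. Without it, Eln fell to 1398 CPM, or 0.697 times the level in fibroblast-like cells, and Fbln5 to 0.0846 times. The cushion matrix gene Hapln1 passed in endocardial-like cells at 4.12 times (5.20 and 2.69, range 1.98 to 5.31), though the fibroblast-like cluster of 171 cells was higher (ratio 0.607), and the basement membrane gene Nid2 in vascular endothelial-like cells at 2.60 times (2.27 and 3.03, range 1.14 to 3.44). The low ends for Lama5 and Nid2 came from adding the epicardial-like class. The list total was 1.83 times higher in smooth muscle-like than in fibroblast-like cells (2.15 and 1.53), but Eln made up 58.8% of it there, and without the cluster of 152 cells the ratio was 0.525. Without Eln, a test added after the values were seen, fibroblast-like cells led at 18383 CPM (17997 and 18803) against 15325 CPM (16729.7 and 13962). Of the 46 genes, 26 were highest in fibroblast-like and 8 in smooth muscle-like cells, and the total was lowest in cardiomyocyte-like cells at 1470.0 CPM.

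Fatty acid oxidation genes separated cardiomyocyte-like cells from the rest, and glycolysis genes did so less clearly. Of 23 fatty acid oxidation genes, 15 passed the size rule, all in cardiomyocyte-like cells, and the list summed to 6121 CPM there, 3.48 times the next class (3.65 and 3.36). The acyl-CoA synthetase gene Acsl1 was 8.82 times the next class (7.44 and 8.30, range 4.73 to 12.3), the pyruvate dehydrogenase kinase gene Pdk4 8.44 times (8.36 and 6.53, range 4.45 to 12.4) and the fatty acid binding protein gene Fabp3 5.86 times (7.35 and 4.86, range 2.17 to 12.7). Of 21 glycolysis genes, 3 passed, all muscle forms: Pfkm at 4.45 times (6.42 and 3.06, range 2.22 to 6.29), Eno3 at 4.15 times (4.60 and 3.71, range 1.57 to 14.7) and Pgam2 at 3.67 times (4.14 and 3.32, range 1.82 to 8.80). The glycolysis list as a whole was 1.30 times higher in cardiomyocyte-like than in pericyte-like cells (1.35 and 1.23), or 1.84 times the next class without mitochondrial and haemoglobin genes. Of 21 glycolysis genes, 11 were highest in cardiomyocyte-like and 5 in macrophage-like cells. The number of glycolysis genes passing was 0 at resolution 2.0 and with fewer variable genes and components. It was 6 without technical replicate 2, where the size rule had to hold in technical replicate 1 alone and was looser by construction. Fatty acid oxidation genes passing numbered 8 at resolution 2.0.

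Of 17 imprinted growth genes, 5 passed the size rule, 4 of them in endocardial-like cells. The fetal growth factor gene Igf2 was 7.38 times the next class (7.03 and 7.77, range 6.59 to 9.84), its neighbouring noncoding RNA H19 was 7.22 times (6.92 and 7.58, range 6.98 to 7.86) and the zinc finger gene Plagl1 was 7.13 times (7.17 and 7.11, range 4.96 to 7.95). The list total of 14599 CPM in endocardial-like cells was 2.42 times that of the next class (2.46 and 2.38), but H19 and Igf2 made up 75.3% of it. Without these 2 genes, a test added after the values were seen, fibroblast-like cells led at 4614 CPM (4494 and 4745) against 3609 CPM in endocardial-like cells (3691 and 3528). Of 16 genes with enough counts, 6 were highest in endocardial-like cells. Mest passed in vascular endothelial-like cells at 3.31 times (3.10 and 3.55, range 2.60 to 3.76).

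Few genes that respond to tissue digestion passed the size rule in any class, though the rule finds only a class that is high. Immediate early genes summed to 2372 CPM in fibroblast-like and 2236 CPM in vascular endothelial-like cells, and to a low of 333 CPM in cardiomyocyte-like cells (327 and 339). Without mitochondrial and haemoglobin genes in the total, cardiomyocyte-like cells were still lowest, at 514 CPM against 1511 CPM in pericyte-like cells, the next lowest. Only the phosphatase gene Dusp1 passed the size rule among 21, at 2.47 times the next class in vascular endothelial-like cells (2.34 and 2.53, range 1.91 to 2.68). Leaving out either technical replicate gave 2 or 3 passing genes, but the rule then had to hold only in the other and was looser by construction. Among 14 heat shock genes only the co-chaperone gene Bag3 passed, at 2.11 times in cardiomyocyte-like cells (2.16 and 2.05, range 1.06 to 3.08). The heat shock list was highest in pericyte-like cells at 4542 CPM (4566 and 4513), and it was lowest in cardiomyocyte-like cells at 2536 CPM, but lowest in smooth muscle-like cells without mitochondrial and haemoglobin genes. Mitochondrial genes took 35.2% of all counts in cardiomyocyte-like cells and from 4.76% to 8.81% in the other compared classes.

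Cell cycle transcripts were lowest in cardiomyocyte-like cells among the 7 classes. The S phase list summed to 651 CPM there (658 and 644) against 1098 CPM in the next lowest class, endocardial-like cells, and was highest in pericyte-like cells at 2279 CPM (2138 and 2455). The G2M list summed to 1963 CPM in cardiomyocyte-like cells (1964 and 1962) and 6954 CPM in pericyte-like cells (6402 and 7639). Without mitochondrial and haemoglobin genes in the total, the gap to endocardial-like cells was small, with 1006 against 1179 CPM for the S phase list and 3032 against 3117 CPM for the G2M list. After thinning to 2000 counts, 42.6% of cardiomyocyte-like cells (41.9% and 43.4%) and 75.1% of fibroblast-like cells (75.2% and 75.1%) had at least 3 counts of these lists. The other classes lay between 68.9% and 87.7%, and the unnamed barcodes reached 83.0%. Among cardiomyocyte-like cells, 2 clusters with 11800.4 and 18969 CPM of these lists held 515 cells, or 9.54% of the class (9.88% and 9.16%). In fibroblast-like cells, 1 cluster with 17942 CPM held 12.7% of the class (14.6% and 10.7%). The lists hold widely expressed genes, so no share of dividing cells was read from them, and the cardiomyocyte-like share depended on thinning, with 21.7% at 1000 counts and 84.6% without thinning.

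Sarcomere isoforms were compared within cardiomyocyte-like cells, where paired genes tell fetal from mature and atrial from ventricular muscle. Myh7, the slow myosin heavy chain that precedes Myh6 in fetal mouse ventricle, took 13.2% of the counts of the pair (13.0% and 13.6%). Tnni1, the fetal troponin I, took 39.3% of its pair with the mature Tnni3 (39.5% and 39.1%). Acta1, skeletal actin, took 0.412% of its pair with cardiac Actc1 (0.413% and 0.411%), and in a cluster of 91 cells it had 0 of 3679 counts, which allows a share of up to 0.0815%. Myl2, the ventricular light chain, took 53.8% of its pair with atrial Myl7 (54.9% and 52.6%), Myl3 67.7% of its pair with Myl4 (68.8% and 66.4%). Nppb took 4.49% of its pair of natriuretic peptides with Nppa (4.41% and 4.57%), but 19.5% by the mean over cells and 1.86% without barcodes over 20% mitochondrial counts.

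These averages joined clusters of different kinds. In the 2 largest clusters, with 2217 and 1099 cells, Myl2 took 97.8% and 97.3% of its pair, Myl3 98.7% and 97.8%, Myh7 16.0% and 19.6%, and Nppb 54.9% and 45.0%. In the next 2 clusters, with 701 and 641 cells, Myl2 took 2.21% and 1.92%, Myh7 1.46% and 0.746%, Nppb 1.16% and 0.743%, and Tnni1 29.5% and 29.3%. The atrial genes Sln and Mybphl were also highest in these clusters, at 8225 and 5837 CPM for Sln and 359 and 416 CPM for Mybphl. The 2 small clusters rich in cycle transcripts lay on either side, with Myl2 at 91.8% and 2.80%. A cluster of 91 cells joined both kinds, with Myl2 at 50.2% (55.9% and 43.3%) and Myl3 at 53.9%. Of its barcodes with enough counts, 66.7% had a Myl2 share over 80% and 30.0% a share under 20%. Leaving out barcodes over 20% mitochondrial counts lowered the Myl2 share of the class to 27.8%, the Myl3 share to 40.1% and the Myh7 share to 8.44%. In fibroblast-like cells, which should lack both genes, Myl2 took 58.6% of the counts of the pair.

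**Figure D3:**
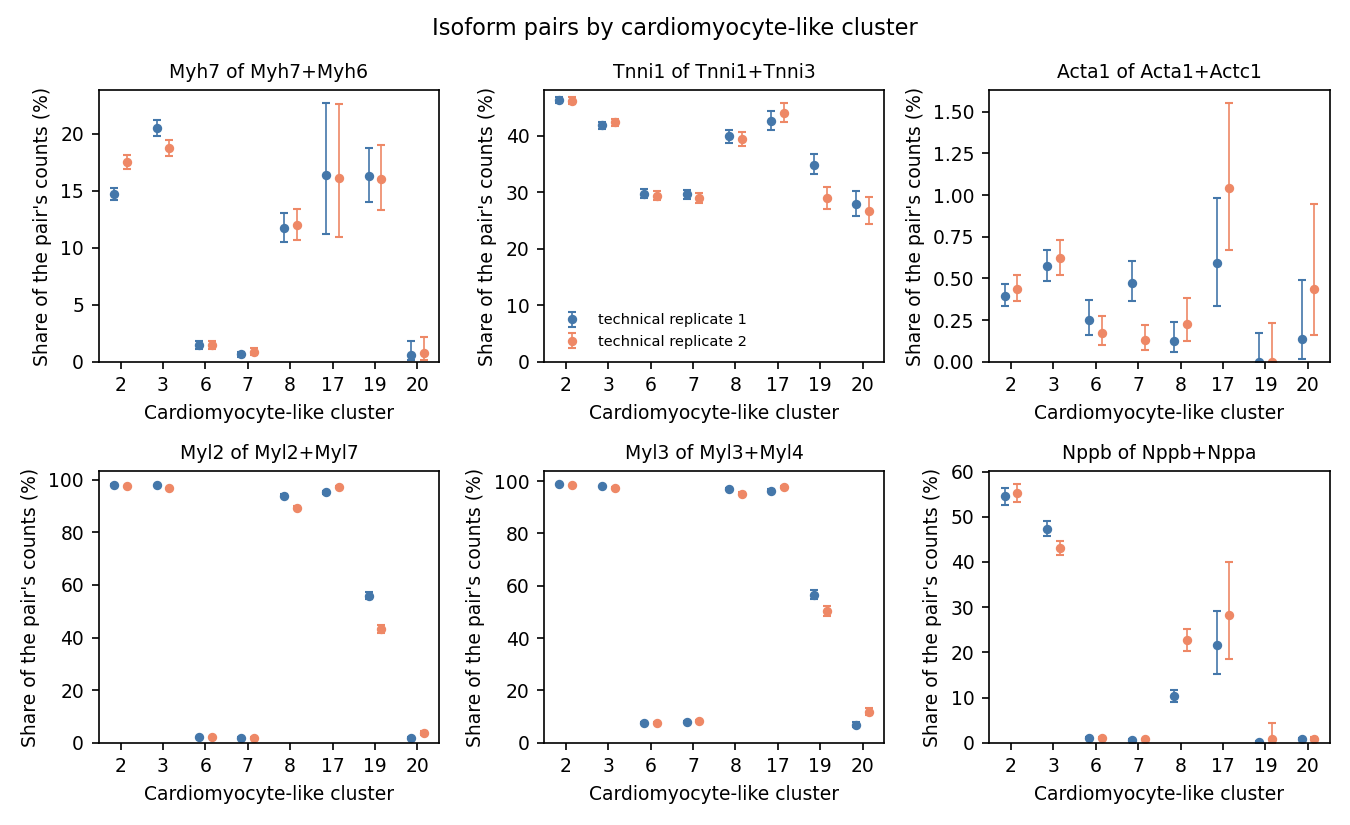
Share of each isoform pair's counts taken by its first gene, in percent, for the 8 cardiomyocyte-like clusters in order of size, with 1 point per technical replicate, exact 95% intervals that cover counting error only, and a scale of its own for each pair. Myl2 took 97.8% and 97.3% of its pair in the 2 largest clusters and 2.21% and 1.92% in the next 2.

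Transcripts of other cell types set the background for shares of cells with a count, and free RNA was not separated from several cells in 1 barcode as their source. Haemoglobin genes had a count in 98.4% of vascular endothelial-like cells (97.4% and 99.4%, median depth 7034 counts) and 91.3% of cardiomyocyte-like cells (median depth 6151 counts), and after thinning to 2000 counts in 78.1% of vascular endothelial-like cells. Cardiomyocyte markers had a count in 98.2% of vascular endothelial-like and 96.5% of fibroblast-like cells (median depth 5687 counts). Myl2 alone had a count in 82.1% of fibroblast-like and 93.8% of cardiomyocyte-like cells, but its level was 599 CPM in the first and 5292 CPM in the second. Shares of cells with a count therefore do not separate these classes, and levels are given in their place. Levels hold the same background, which was not subtracted, so it may limit the ratios of a class to the next.

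Sex-linked transcripts were counted to see if the suspension held cells of both sexes. Xist, the noncoding RNA of the inactive X chromosome, had a count in 94.3% of kept cells (94.6% and 94.0%). Xist alone was seen in 11065 cells, neither Xist nor a Y-linked gene in 672, and both in 7. No cell had a Y-linked count without Xist, and 0 of 11744 cells allows a share of such cells of up to 0.0255%, which is not a limit on male cells. The Y-linked genes Ddx3y, Kdm5d and Uty summed to 7 counts (6 and 1) and Eif2s3y had 0, while Xist had 81805 counts. These values argue against a large share of male cells, though a small share stays possible. Tsix, the antisense gene of Xist, had 4.72 CPM in cardiomyocyte-like and 14.5 CPM in endocardial-like cells, where Xist had 961 and 2428 CPM. At least 2 counts of Xist were seen in 85.2% of cells.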

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

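The split of left-out barcodes by a limit of 50% of counts was chosen after the data were seen. The cell filter set aside 186 barcodes with under 500 genes (84 and 102 in technical replicates 1 and 2), which entered no comparison although their median depth of 4292 counts was close to that of kept cells. Haemoglobin genes took over 50% of the counts in 57 of them (23 and 34), which drew attention as a signal in unused barcodes above the limit that a count of 0 allows. Mitochondrial genes took over 50% of the counts in the other 129 (61 and 68), which drew attention in the same way. Among kept barcodes, 4 had over 50% of counts from haemoglobin genes (3 and 1). With the minimum lowered to 200 genes, 66 cells formed a cluster that met the erythroid naming rule.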

How the results depend on the processing

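Tests with the highest 5% of doublet scores left out, classes of at least 20 cells, thinning to 1000 counts that are not mitochondrial, and approximate neighbours were chosen after seeing the data, and the cause of a change was not tested unless stated. The counts of imprinted genes and ligands passing the size rule stayed within 1.5 times their value in 16 of 16 alternatives. Of 770 values for named gene ratios, 510 moved by no more than 1 SD between the technical replicates, 252 moved further and 8 reversed. That SD rests on 2 values, so a ratio that differed more between the technical replicates counted more easily as unmoved. For this SD the epicardial-like class was also large enough to be compared in technical replicate 2 but not in technical replicate 1. At resolution 2.0 the ratios reversed for Sema3c (0.357), Il1b (0.555), Wnt5a (0.227) and Wt1 (0.340), and the counts passing were 0 for glycolysis, 8 for fatty acid oxidation, 2 for immediate early and 0 for heat shock genes. With classes of at least 20 cells, where the epicardial-like class joins by construction, Sema3c (0.338), Wnt5a (0.216) and Wt1 (0.303) reversed, with 2 immediate early and 0 heat shock genes. With 1000 variable genes and 15 components Il1b reversed (0.521), with 0 glycolysis and 0 heat shock genes. With 1 technical replicate left out, the size rule had to hold only in the other, so it was looser by construction. This gave 2 to 3 immediate early genes, 3 to 6 glycolysis genes and a fibroblast-like cycle share of 74.4% to 75.1%. Without technical replicate 2 the epicardial-like share was 0.362%, against 0.603% of technical replicate 1 in the main clustering. A minimum of 200 genes gave 17.0% unnamed barcodes, 17.1% vascular endothelial-like cells, 2 immediate early genes and a fibroblast-like cycle share of 73.9%. Without barcodes over 20% mitochondrial counts, cardiomyocyte-like cells were 25.5% and unnamed barcodes 3.75% of those kept, cycle shares were 54.4% and 74.0% in cardiomyocyte-like and fibroblast-like cells, and Myh7 and Myl2 took 8.44% and 27.8% of their pairs. Doublet calls kept gave 2 immediate early genes and a fibroblast-like cycle share of 73.6%, and the highest doublet scores left out gave 2 and 73.7%. Resolution 0.5 gave 2 immediate early and 0 heat shock genes, and list genes kept among the features gave 2 immediate early genes. The mean over cells gave 0 heat shock genes, and CPM without mitochondrial and haemoglobin genes gave 5 glycolysis genes. A ratio of 3, stricter by construction, left 21 transcription factors, 8 matrix, 6 fatty acid oxidation, 0 immediate early and 0 heat shock genes. In cardiomyocyte-like and fibroblast-like cells the cycle shares were 21.7% and 45.6% at 1000 counts, 84.6% and 95.4% without thinning, 21.5% and 48.0% with at least 5 counts, and 34.6% and 47.3% at 1000 counts that are not mitochondrial. Averaged over cells, Myh7 took 11.2% and Myl2 71.2% of their pairs. With a pseudocount of 0.1 CPM the Pearson r was 0.995, and thinning lowered the vascular endothelial-like haemoglobin share to 78.1%. The T or NK-like class had no share in several settings, among them leaving out either technical replicate, because no cluster took that name. Depth limited the classes of few cells and ratios with 1 to 3 counts in the next class, such as Has2, Gdf6 and Wnt2.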

Other observations

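The comparisons between clusters, the epicardial-like comparison, the free RNA test in empty droplets and the transcript length test were chosen only after the results were seen, as was the need for a whole interval to lie below the change to be explained in the technical replicate tests. Once the epicardial-like class was compared, 4 transcription factors, 6 ligands, 2 matrix genes, 2 imprinted genes and 1 immediate early gene passed the size rule there. Bnc1, a basonuclin of mesothelium, stood at 189 CPM with 2 counts in the next class (ratio 892, interval 242 to 7440). The Wnt agonist gene Rspo1 was 197 times the next class (128 and 329 in technical replicates 1 and 2), and the matrix gene Efemp1 198 times (175 and 238). Wt1 and Tbx18, known epicardial factors, were 3.30 times (3.36 and 3.31) and 3.11 times (2.84 and 3.21) the next class.

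The 2 largest cardiomyocyte-like clusters rich in atrial light chain held 701 and 641 cells. Bmp10 was 30.8 times (29.3 and 32.1), Angpt1 7.39 times (7.06 and 7.77) and Nppb 3.80 times (4.05 and 3.53) higher in the first. A cluster of 91 cells had Bmp2 at 128 times (148 and 127) and Tbx3, a factor of the conduction system, at 22.7 times (18.7 and 29.0) the level of the other cardiomyocyte-like cells. Irx5, Irx3 and Etv1 were 8.01, 6.29 and 9.05 times higher there, and Nppb was 96.3 times higher in the other cells, with 2 counts in the cluster (interval 26.6 to 795). Smooth muscle-like cells split into a cluster with Eln and Fbln5 at 31.8 and 185 times the other's level and one with Tbx2 and Sparcl1 at 31.0 and 47.7 times. A fibroblast-like cluster of 171 cells had the tendon factor Scx at 29.1 times (28.7 and 29.8) and Rspo3 at 97.9 times (62.0 and 191) the level of the largest fibroblast-like cluster.

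The design holds 1 group, so no biological explanation was tested for the next 3 patterns. The unnamed barcodes had low depth, haemoglobin and markers of several cell types. Their median haemoglobin count was 3.3 times that of the highest named class (2.60 and 3.36), but haemoglobin is what set them apart, so free RNA in otherwise empty droplets cannot be told apart from other sources. Among 2575 of them with enough counts, 76.0% had a Myl2 share between the atrial and ventricular extremes, against at most 4.30% in any cardiomyocyte-like cluster, so RNA of several cells in 1 barcode may account for them. Mixed free RNA would give the same shares, so the source stays open.

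A cardiomyocyte-like cluster of 133 barcodes had Malat1, a nuclear RNA, in 45.9% of them against 99.7% of the other cardiomyocyte-like cells, and a median of 0.917% mitochondrial counts against 36.6%. Shallow sequencing was argued against, since 90.5% of the other cells kept an Xist count after thinning to its depth, against 9.77% in the cluster. Cytoplasm without a nucleus may account for the low Malat1, as the median ratio of 3 other nuclear RNAs was 0.0478. That median rested on 1 count of Neat1 (interval 0.00121 to 0.267), 0 of Kcnq1ot1 and 9 of Meg3. Loss of long transcripts may also account for the low Malat1. Transcript length and the log2 ratio had a Spearman rho of -0.595 across 1047 genes, with mitochondrial genes left out. The nuclear RNAs tested are long, and 20 of 199 other genes over 5000 nt fell as far as Malat1, so both stay open for the low Malat1. Neither test covered mitochondrial genes, so no explanation of the low mitochondrial share was tested.

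Technical replicate 2 had more haemoglobin counts per barcode by the median in every class, though not by summed CPM in macrophage-like, pericyte-like and T or NK-like cells, and technical replicate 1 had 1.28 to 1.51 times more Malat1 in the 7 compared classes. More free RNA in technical replicate 2 predicted higher cardiomyocyte genes in fibroblast-like and vascular endothelial-like cells. Their median ratio was 1.16 with an interval of 0.997 to 1.33 and single genes from 0.868 to 2.40, against a haemoglobin ratio of 1.2 in vascular endothelial-like and 1.54 in fibroblast-like cells, so this and other sources of the difference cannot be told apart. The limit of 1.2 set in advance for excluding it was met by the median but not by its interval. A higher share of nuclear RNA in technical replicate 1 was argued against by the median ratio of the other nuclear RNAs. This median was 1.02 (interval 0.967 to 1.08), below the smallest Malat1 ratio, with single values from 0.676 to 2.03. Both intervals of medians treat the same few genes in several classes as independent values, 12 and 27 in number, so they may be too narrow.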
